A study of Mus musculus with 9 samples.

How the data were processed

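Retinal RNA from adult male C57BL/6 mice was measured on 9 Agilent mouse gene expression arrays, 3 for each of 3 groups. Per the labels, the right eye of each mouse received an intravitreal injection of phosphate-buffered saline (PBS), AAP or HAN, and the retinas were taken 7 days later. The series title describes AAP and HAN as high-affinity peptides that target vascular endothelial growth factor (VEGF); a dose of 1 µM is given in the labels, which word it for PBS as well. There were 12 mice in a group, and 4 retinas were pooled into each sample, so an array measured a pool and not a mouse. The p-values of the single-gene tests therefore measure the spread between 3 pools in a group. Total RNA was extracted with Trizol and labelled with a single dye, Cy3, per the labels' protocols.

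The authors deposited the scanner output of each array and a value table. Per the file headers, spot intensity was quantified with Agilent Feature Extraction 11.0.1.1 under the protocol GE1_1100_Jul11, and the array design was annotated on the mouse build mm9. Per the file headers, the processed signal is an intensity on a linear scale that was background-subtracted and spatially detrended within each array, and was not normalised between arrays. The authors' deposited value table was set against the scanner values. In each array at least 99.7% of its values equalled the mean processed signal over a probe's spots within a relative tolerance of 0.0001, and the unequal ones all belonged to probes with several spots. The table is thus the same linear intensity without normalisation between arrays, and its scale, centring and direction were settled by this comparison. Its column medians were 298.3 (PBS 1), 256.4 (PBS 2), 231.9 (PBS 3), 265.5 (AAP 1), 237.6 (AAP 2), 164.7 (AAP 3), 251.1 (HAN 1), 242.5 (HAN 2) and 296.5 (HAN 3). How the authors compared the groups is not given in the sources used here.

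Each array held 44397 spots, of which 43020 were not controls. Control spots and spots that Feature Extraction marked as non-uniform or population outliers were left out (103 to 160 outlier spots on an array), and no spot was saturated. The processed signal was put on the log2 scale and the array's 75th percentile was subtracted. Spots of a probe were averaged, which gave 39429 probes. A probe was kept where all arrays of at least 1 group were well above background, and a gene was represented by its kept probe with the highest mean over the 9 arrays. The 75th percentile of the processed signal ran from 1334 (AAP 3) to 2343 (PBS 1), and 71.6% to 79.2% of spots were well above background. The number of arrays limits the precision. Half-widths of the 95% confidence intervals had a median of 1.18-fold in each comparison.

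The files hold no gene symbol column, so probes were named by matching their transcript accession, without versions, to a reference gene table of the assembly GRCm38.p6. That matched 26055 probes to 19751 symbols; 13374 probes kept their accession as a name, and no coordinates were taken from the table. Where probes of a named gene disagreed in direction, this is stated beside the gene. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal.

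The comparisons AAP against PBS, HAN against PBS and AAP against HAN came from a single limma 3.58.1 model (R 4.3.3) with a mean per group over all 9 arrays. limma's lmFit and eBayes were used two-sided, with Benjamini-Hochberg adjustment over 23895 genes and a threshold of adjusted p under 0.05. The fit had 6 residual and 1.83 prior degrees of freedom. A set of 35 gene lists was tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. A list needed at least 5 measured genes, which left 34; 743 of the 753 list symbols were on the array. At the preset correlation, camera sets the genes of a list against other genes nearly as if they varied independently. Its p-values thus leave out most of the spread that the genes of a list share between pools. The estimated correlation was 0.40 for gliosis, 0.70 for microglia, 0.75 for interferon and 0.96 for lens. The lists, the tests, the threshold, the groups and the alternatives were chosen before the data were examined, except where stated.

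The rule for named genes was also set before the data were examined. It took, in each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with groups that did not overlap, limited to curated RefSeq messenger RNAs with a proper symbol. If fewer than 10 passed, the 10 with the smallest p were taken as genes that did not pass. Vegfa, Kdr, Flt1, Nrp1 and Pgf, up to 4 members with the smallest p from each list described, and fixed readouts that include Gfap, Opn1sw, Aif1 and Cryaa were taken in every comparison. Some genes the rule took are left out of the text.

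The arrays lay on 3 slides, each scanned in a session of its own: slide 1 held the 3 PBS arrays and AAP 1, slide 2 held AAP 2, AAP 3, HAN 1 and HAN 2, and slide 3 held HAN 3 alone. Slide was tried as a fixed block, as a random block (statmod 1.5.0) and within slide 1 and slide 2. With the fixed block, AAP against PBS rests on AAP 1, and HAN against PBS is chained through AAP because no slide held both groups. Differences between AAP 1 and the other AAP pools thus enter every blocked value of HAN against PBS. The other alternatives were normexp background correction with an offset of 50 (on the median spot signal, since the files hold no mean signal), quantile normalisation, median scaling, no filter on dim probes, only probes above background on all arrays, every probe tested, the value table, the replicate number as a block with and without slide, only the compared groups in the fit, eBayes with trend and robust settings, array weights and leaving out each array. A run without AAP 1 and AAP 3, and a run with the lens and muscle list levels as covariates, were added after the data were seen. Where a single AAP array remained, it was assumed to vary like the other groups.

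The steps were tested on simulated data that took each gene's mean and spread from these arrays. In them 200 genes were changed by known folds, 50 at each fold, and the microglia list was shifted by -0.3. Genes were drawn independently and with the same spread in all groups, so the wider spread of AAP and tissue differences between pools were absent. The recovery is thus not the power in these data, and its differences between comparisons came from separate draws of genes. For AAP against PBS, HAN against PBS and AAP against HAN, the gene test recovered 8%, 8% and 8% of genes changed 1.25-fold, 62%, 36% and 46% at 1.5-fold, 74%, 74% and 68% at 2-fold and 88%, 88% and 92% at 4-fold; it called 5, 6 and 5 unchanged genes. Exact permutation tests and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.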

Results

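The series asked how gene expression in the retina is altered by AAP and HAN, a pair of peptides that target VEGF, the growth factor that drives blood vessel growth and leakage. Retinal pools were compared 7 days after injection into the eye, with PBS as the negative control and 3 arrays in each group. The 9 arrays were close to one another: Pearson's r across genes was 0.980 to 0.995 in the 9 pairs within a group and 0.979 to 0.995 in the 27 pairs between groups. The median SD of a gene over the arrays of a group was 0.10 on the log2 scale in PBS, 0.14 in AAP and 0.10 in HAN. AAP 3 stood apart on the first principal component (29.9% of the variance) and AAP 1 on the second (27.4%).

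Transcripts of tissues next to the retina differed between pools of the same group. Skeletal muscle markers, 14 of which were measured, stood on average 5.30 (AAP 1) and 4.03 (AAP 3) above the PBS mean on the log2 scale, against -0.35 in AAP 2 and between -0.15 and -0.07 in the 3 HAN pools. Myoglobin (Mb), which stores oxygen in muscle, was 505-fold above the PBS mean in AAP 1 and 164-fold above it in AAP 3. The myosin genes Myl1 and Myh4 were 281-fold and 497-fold above it in AAP 1. Lens crystallins and lens fibre markers, 23 of which were measured, ranged from -2.17 (PBS 2) to 1.16 (PBS 1) within PBS and from -2.06 (AAP 3) to 2.29 (AAP 2) within AAP. They lay between 0.58 and 1.44 in HAN. Cornea, iris and ciliary body markers ranged from -1.14 to 1.35 within PBS, from -1.98 to 0.86 within AAP and from -0.42 to -0.01 within HAN.

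**Figure D1:**
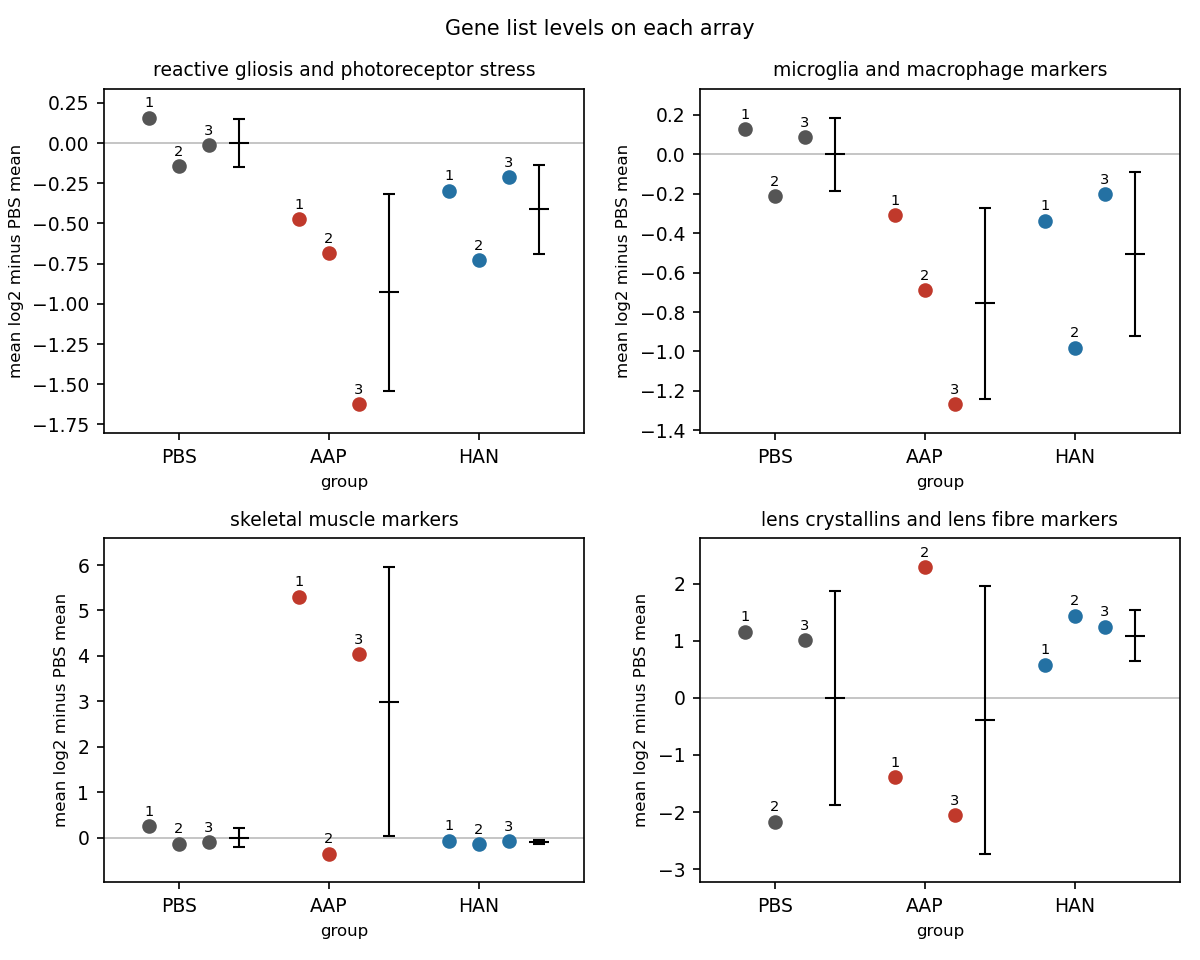
Mean log2 level of 4 gene lists on each array, minus the PBS mean (vertical axis), by group (horizontal axis); points are the 3 arrays of a group with their number, and dashes with bars are the group mean and SD. The gliosis and microglia lists lie lowest in AAP 3, the muscle list is high in AAP 1 and AAP 3 alone, and the lens list spreads from -2.17 to 1.16 within PBS.

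The comparison of AAP with PBS asked which retinal transcripts differ after AAP. Genes of microglia, reactive glia, complement and inflammation were lower as groups in the AAP retinas. Of 26 measured microglia and macrophage markers 25 were lower, by a median of -0.73 on the log2 scale (camera adjusted p = 9.54e-13; adjusted p = 0.564 with an estimated correlation), and of 30 genes of reactive gliosis and photoreceptor stress 28 were lower, by a median of -0.74 (adjusted p = 1.35e-11; adjusted p = 0.564 with an estimated correlation). Among them were Timp1, an inhibitor of matrix metalloproteinases (log2 change -2.39, 95% interval -3.52 to -1.26), Gfap, the intermediate filament of reactive Mueller cells and astrocytes (-1.27, -2.25 to -0.28), and Aif1, a marker of microglia (-0.73, -1.39 to -0.07). None of these 3 genes passed the test over all genes on its own (limma adjusted p = 0.623, 0.673 and 0.708).

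Other members of these groups had values in the same range without passing singly (limma adjusted p from 0.614 to 0.712). In the gliosis list, the acute-phase gene Lcn2 differed by -1.69, the transcription factor Cebpd by -1.42 and Atf3 by -0.78. In the microglia list, the lysozyme gene Lyz2 differed by -1.96, Laptm5 by -1.06, the Fc receptor subunit Fcer1g by -0.72 and the complement gene C1qb by -0.90. The 21 complement and coagulation genes had a median of -0.74, with 16 lower and 5 higher (camera adjusted p = 1.94e-06; adjusted p = 0.564 with an estimated correlation); C1qa was at -0.91, Cfi at -0.86 and the plasminogen activator Plat at -0.72. Of 19 inflammatory cytokine and adhesion genes 18 were lower, median -0.45 (adjusted p = 1.57e-07; adjusted p = 0.564 with an estimated correlation). They included the chemokines Ccl2 (-2.26) and Ccl3 (-1.29), Vcam1 (-0.45) and the cytokine receptor Tnfrsf12a (-0.76).

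The gliosis and microglia lists differed between pools of the same group. The gliosis list stood at -0.47, -0.69 and -1.63 against the PBS mean in AAP 1, AAP 2 and AAP 3, and the microglia list at -0.31, -0.69 and -1.27. The complement list was at 0.20, -0.73 and -1.19, against 0.37, -0.39 and 0.02 in PBS 1, PBS 2 and PBS 3. The inflammatory list was at -0.23, -0.60 and -1.37, against 0.16, 0.07 and -0.24. For complement and inflammation, AAP 1 thus lay within the PBS range. Muscle markers, at 5.30, -0.35 and 4.03, did not follow this order, while cornea, iris and ciliary body markers, at 0.86, -0.05 and -1.98, did. Other lists did as well, among them pigment epithelium (0.22, -0.18 and -0.55) and barrier junctions (0.21, -0.04 and -0.69). These are means over a list. The medians of the cornea, iris and ciliary body list, at -0.29, -0.06 and -2.06, did not follow the order. Within PBS the gliosis list was at 0.16, -0.14 and -0.01 and the cornea, iris and ciliary body list at 1.35, -1.14 and -0.22 in PBS 1, PBS 2 and PBS 3. In AAP 2, the pool without raised muscle markers, compared alone with PBS after the data were seen, the medians were -0.46 for gliosis, -0.67 for microglia, -0.74 for complement and -0.48 for inflammation, values of a single array. With slide as a fixed block, which rests on AAP 1 and equals its value within slide 1, they were -0.48 (adjusted p = 0.0321), -0.36 (adjusted p = 0.0186), -0.28 (adjusted p = 0.932) and -0.16 (adjusted p = 0.248). The block thus ended the calls of the complement and inflammatory lists, and put Timp1 at -2.00, Gfap at -0.86 and Aif1 at -0.33. Without AAP 3 the gliosis median was -0.39 (adjusted p = 2.35e-08), and without AAP 1 the inflammatory median was -0.84 (adjusted p = 7.68e-10).

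Antigen presentation, interferon, Mueller glia and immediate early genes were also lower as lists in AAP, and were more dependent on single pools. The antigen presentation list had 18 of 19 genes lower with a median of -0.35 (camera adjusted p = 0.00150; adjusted p = 0.834 with an estimated correlation). B2m, the light chain of class I molecules, was at -0.72 there, and H2-K1, H2-Q7 and H2-D1 were at -0.46, -0.35 and -0.35. The list had a median of -0.10 without AAP 3 (adjusted p = 0.276), -0.23 without PBS 1, -0.60 without AAP 1 and 0.07 with slide as a block, as within slide 1 (adjusted p = 0.333). The interferon-stimulated list had 24 of 26 genes lower with a median of -0.33 (adjusted p = 0.00214; adjusted p = 0.843 with an estimated correlation), including Cxcl10 (-2.59, well above background in 2 of the 3 AAP arrays), Ifitm3 (-0.70) and Bst2 (-0.62); Iigp1 was at 0.24, with another probe at -0.42. Its median was -0.00 without AAP 3 (adjusted p = 0.979), -0.08 without PBS 2 (adjusted p = 0.323), 0.01 in AAP 2 alone, -0.10 with array weights (adjusted p = 0.405) and -0.01 with slide as a block, as within slide 1, where the test pointed higher (adjusted p = 0.932). It was -0.51 without AAP 1, -0.61 without AAP 2 and -0.53 without PBS 3.

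In the Mueller glia and astrocyte list 15 of 21 genes were lower, with a median of -0.12 (adjusted p = 0.0138; adjusted p = 0.564 with an estimated correlation). Crym differed by -0.56, apolipoprotein E (Apoe) by -0.43, Aldh1l1 by -0.33 and the water channel Aqp4 by -0.30. Of 20 immediate early genes 13 were lower, with a median of -0.19 (adjusted p = 0.0424; adjusted p = 0.834 with an estimated correlation). Egr2 was not well above background in any AAP array and was at least 2.25-fold lower than in PBS (limma adjusted p = 0.631), Jun was at -0.24 and Egr4 at 0.70. With slide as a block, as within slide 1, these lists had medians of -0.16 (adjusted p = 0.0744) and -0.09 (adjusted p = 0.945). The Mueller list did not pass without AAP 3 (-0.12, adjusted p = 0.123) or PBS 1 (-0.08, adjusted p = 0.0536). The immediate early list did not pass without AAP 2 (-0.16, adjusted p = 0.258), AAP 3 (-0.13, adjusted p = 0.155), PBS 1 (-0.13, adjusted p = 0.152) or PBS 3 (-0.15, adjusted p = 0.196). Without AAP 2 or PBS 2 the Mueller median was -0.20. The immediate early list also did not pass with normexp (-0.07, adjusted p = 0.0977), quantile normalisation (-0.21, adjusted p = 0.0685), no filter on dim probes (-0.14, adjusted p = 0.0516) or only probes above background on all arrays (-0.09, adjusted p = 0.256). Nor did it with the replicate block (-0.19, adjusted p = 0.0525) or slide as a random block (-0.19, adjusted p = 0.0688).

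The lists that were higher in AAP were skeletal muscle and retinal ganglion cell markers. All 14 muscle genes were higher, with a median of 3.24 (camera adjusted p = 4.56e-10; adjusted p = 0.564 with an estimated correlation). The skeletal actin Acta1 was at 2.35, the light chain Mylpf at 1.90, the calcium pump Atp2a1 at 1.38 and Pvalb at 1.11 (limma adjusted p from 0.646 to 0.693). The median was 5.53 with slide as a block, as within slide 1 (adjusted p = 4.07e-16), 1.83 without AAP 1, 4.98 without AAP 2 and -0.36 in AAP 2 alone. Of 24 ganglion cell markers 19 were higher, with a median of 0.09 (adjusted p = 0.0401; adjusted p = 0.843 with an estimated correlation), and the median was 0.04 with slide as a block, as within slide 1 (adjusted p = 0.945). The transcription factor Pou4f2 was at 0.30 and the neurofilament gene Nefh at 0.26, while osteopontin (Spp1) was at -0.84 and Gap43 at -0.16. The ganglion list did not pass without AAP 2 (0.08, adjusted p = 0.108), AAP 3 (0.09, adjusted p = 0.228) or PBS 2 (0.05, adjusted p = 0.582), and its median was 0.15 without AAP 1 or PBS 3. Nor did it pass with array weights (0.06, adjusted p = 0.403), no filter on dim probes (0.09, adjusted p = 0.270), only probes above background on all arrays (0.09, adjusted p = 0.0577) or slide as a random block (0.09, adjusted p = 0.130).

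No named gene of the VEGF pathway passed between AAP and PBS. Vegfa, the ligand both peptides target, was at 0.04 (95% interval -0.16 to 0.23). Another Vegfa probe, dimmer and outside this interval, was at 0.24. The receptors Kdr and Flt1 were at -0.12 (-0.37 to 0.13) and 0.11 (-0.09 to 0.30), the co-receptor Nrp1 at -0.26 (-0.56 to 0.03) and placental growth factor (Pgf) at -0.45 (-0.94 to 0.03). The limma adjusted p was 0.94 for Vegfa, 0.842 for Kdr, 0.826 for Flt1, 0.723 for Nrp1 and 0.72 for Pgf. With slide as a block the 5 genes were at 0.13, -0.23, 0.17, -0.32 and -0.51. The list of 10 VEGF ligands and receptors, with Vegfb at -0.11 and Vegfc at 0.13, had a median of -0.07 (camera adjusted p = 0.352), as with slide as a block (-0.07, adjusted p = 0.422). The cone opsin Opn1sw was at -0.28 and the lens crystallin Cryaa at -0.31.

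**Figure D2:**
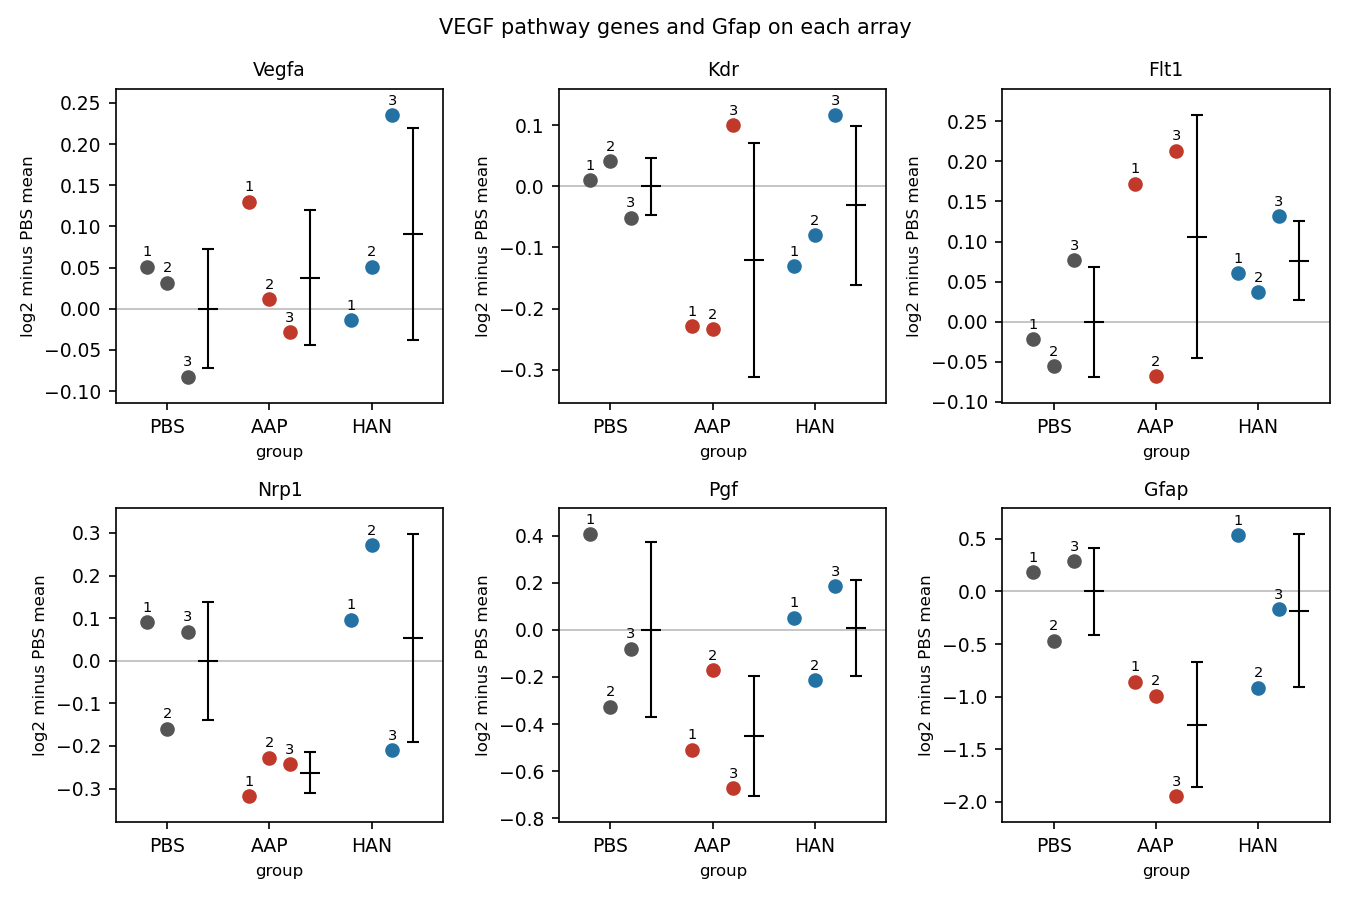
Log2 level of 5 VEGF pathway genes and Gfap on each array, minus the PBS mean (vertical axis), by group (horizontal axis); points are the 3 arrays of a group with their number, and dashes with bars are the group mean and SD. Vegfa, Kdr and Flt1, on the probe tested for each gene, stay close to PBS in both peptide groups, and Gfap lies lowest in AAP 3.

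The gene test called 1 transcript higher and 0 lower in AAP than in PBS, and 1631 genes had an unadjusted p under 0.05 in limma against 1194.75 by chance (911 higher, 720 lower). The groups did not overlap in 12.2% of genes, where chance gives 10%, and 96.5% of genes differed by less than 1.5-fold. The called transcript, ENSMUST00000072628, has no symbol in the tables used here and was chosen after its values were seen; it rose by 1.21 on the log2 scale (SE 0.09, limma adjusted p = 0.0265), from -4.59 ± 0.09 in PBS to -3.38 ± 0.14 in AAP (SD, n = 3). Its change was 1.07 with slide as a block, as within slide 1 (adjusted p = 0.0418). It did not pass without AAP 3 (adjusted p = 0.133), PBS 1 (adjusted p = 0.270), PBS 2 (adjusted p = 0.192) or PBS 3 (adjusted p = 0.233), and over all alternatives its adjusted p ran from 0.0165 (probes above background on all 9 arrays) to 1.00 (normexp background correction).

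The 10 curated genes with the smallest p did not pass. The muscle ring finger gene Trim54, not well above background in PBS, was at least 2.73-fold higher in AAP (limma adjusted p = 0.109), and the muscle phosphoglycerate mutase Pgam2 was at 1.78 (adjusted p = 0.614). Clrn1, an Usher syndrome gene, was at -0.55 (-0.69 to -0.40, adjusted p = 0.158). Cwc25 was at 0.42 (adjusted p = 0.536), and Kalrn (-0.36), Ticam1 (-0.33), Tnfrsf12a, Pid1 (-0.33), Vps33b (0.30) and Gcm1 (0.49) had adjusted p of 0.614 to 0.623; the probes of Kalrn disagreed in direction. Adjusted over the list alone, 9 lists had 1 member past the threshold: Timp1 in the gliosis and matrix lists, Tnfrsf12a, Egr2, Spp1, Myh11 (pericyte list), Mylpf, Ciart (clock list) and Ermn (pigment epithelium list).

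Apart from the VEGF list, the remaining tested lists did not pass in AAP against PBS (camera adjusted p from 0.162 to 0.822). Their medians were 0.03 for rod phototransduction and outer segment, -0.07 for cone phototransduction, 0.05 for bipolar cells, -0.03 for amacrine and horizontal cells, 0.06 for endothelial cells, 0.05 for pericytes and smooth muscle (mean -0.22, tested as lower), -0.01 for angiogenesis regulators, -0.06 for blood-retina barrier junctions and -0.01 for hypoxia-inducible factor targets. They were -0.00 for neurotrophic factors, -0.09 for apoptosis and p53 targets, -0.06 for the Nrf2 response, -0.02 for the unfolded protein and heat shock response, 0.04 for the circadian clock, -0.03 for the cell cycle, -0.03 for glycolysis, 0.03 for oxidative phosphorylation and -0.02 for extracellular matrix. Lists of other tissues were at -0.31 for lens, -0.39 for cornea, iris and ciliary body, -0.05 for pigment epithelium, -0.15 for erythrocytes and -0.07 for neutrophils and T cells. The 4 measured sex check genes, too few to test, had a median of 0.18. The slide block, which rests on AAP 1, called some of these lists: endothelial cells (0.26, adjusted p = 0.000330), pigment epithelium (0.22, adjusted p = 5.65e-05), cell cycle (0.20, adjusted p = 0.0252), erythrocytes (0.99, adjusted p = 0.0283) and cornea, iris and ciliary body (median -0.29 but tested as higher, adjusted p = 0.0428) as higher. It called rods (-0.12, adjusted p = 0.0252), glycolysis (-0.12, adjusted p = 0.0493) and lens (-1.29, adjusted p = 0.0337) as lower.

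The comparison of HAN with PBS asked the same of HAN. Interferon-stimulated, microglial, antigen presentation and gliosis genes were lower as groups in the HAN retinas. Of 26 interferon-stimulated genes 25 were lower, with a median of -0.49 (camera adjusted p = 7.25e-06; adjusted p = 0.833 with an estimated correlation), among them the tetherin gene Bst2 (-0.92, 95% interval -1.60 to -0.25), Gbp3 (-1.02) and the transcription factor Irf7 (-0.41), with Iigp1 at 0.29 and another of its probes at -0.45. Of 26 microglia markers 25 were lower, with a median of -0.48 (adjusted p = 7.25e-06; adjusted p = 0.833 with an estimated correlation), among them Lyz2 (-1.64), C1qb (-0.73) and the Fc receptor Fcgr1 (-0.38). None of the named members passed singly (limma adjusted p from 0.419 to 0.515).

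The antigen presentation list had 17 of 19 genes lower, with a median of -0.44 (adjusted p = 8.79e-05; adjusted p = 0.833 with an estimated correlation); B2m was at -0.65, H2-D1 at -0.61, H2-T23 at -0.61 and H2-Q7 at -0.55. Of 30 gliosis genes 26 were lower, with a median of -0.23 (adjusted p = 0.000524; adjusted p = 0.833 with an estimated correlation). Fibroblast growth factor 2 (Fgf2) was at -1.05, Atf3 at -0.79 and Mt1 at -0.16, Steap4 was not well above background in HAN and at least 1.62-fold lower than in PBS, and Gfap was at -0.18 (-1.17 to 0.80, limma adjusted p = 0.92). The inflammatory list had 15 of 19 genes lower (median -0.24, adjusted p = 0.00313; adjusted p = 0.833 with an estimated correlation), with Ccl3 at -1.45, Ccl4 at -1.25, Ccl5 at -1.01 and Tnfrsf12a at -0.48. The complement list had 20 of 21 genes lower (median -0.32, adjusted p = 0.00401; adjusted p = 0.833 with an estimated correlation), with C3 at -0.76, C1qa at -0.67 and Plat at -0.56. Itgam, a microglial integrin, was at 0.42 with probes that disagreed, and Aif1 was at -0.59 (-1.25 to 0.08).

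With slide as a fixed block, chained through AAP since no slide held both groups, none of these 6 lists remained lower past the threshold. Their medians were then -0.10 for interferon (adjusted p = 0.776), -0.05 for microglia (adjusted p = 0.985), 0.11 for antigen presentation (adjusted p = 0.227), 0.15 for gliosis (adjusted p = 0.602), 0.11 for inflammation (adjusted p = 0.639) and 0.44, past the threshold and higher, for complement (adjusted p = 0.0437). Per pool, the gliosis list was at -0.30, -0.73 and -0.21 and the microglia list at -0.34, -0.98 and -0.20 in HAN 1, HAN 2 and HAN 3, where the lens list stood at 0.58, 1.44 and 1.24 and the cornea, iris and ciliary body list at -0.01, -0.06 and -0.42. Without PBS 1 the complement list (median -0.16, adjusted p = 0.204) and the inflammatory list (median -0.12, adjusted p = 0.0744) did not pass, and the antigen median was -0.24. With normexp the inflammatory list did not pass (0.01, adjusted p = 0.116). The mean of the interferon list was at -0.09, 0.47 and -0.38 in PBS 1, PBS 2 and PBS 3. In HAN 1, HAN 2 and HAN 3 it was at -0.68, -0.85 and -0.30. HAN 3 thus lay within the PBS range, and PBS 2 raised the PBS mean. Without HAN 2 the medians were -0.26 for microglia, -0.12 for gliosis and -0.12 for inflammation, without HAN 1 the gliosis median was -0.37, and without PBS 2 the complement median was -0.58.

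Rod, mitochondrial and chaperone genes were lower as lists by small amounts in HAN. Of 28 rod genes 24 were lower, with a median of -0.10 (adjusted p = 0.00157; adjusted p = 0.838 with an estimated correlation), including the rod arrestin Sag (-0.30), recoverin (Rcvrn, -0.23) and the transducin subunits Gngt1 (-0.25) and Gnat1 (-0.22). The rod list had a median of -0.33 with slide as a block (adjusted p = 8.02e-06) and -0.18 without PBS 1, and did not pass without PBS 2 (-0.05, adjusted p = 0.0967) or HAN 3 (-0.10, adjusted p = 0.0739). Per pool, the rod list was at -0.16, 0.12 and 0.04 in PBS 1, PBS 2 and PBS 3. It was at -0.11, 0.00 and 0.21 in AAP 1, AAP 2 and AAP 3 and at -0.10, -0.09 and -0.16 in HAN 1, HAN 2 and HAN 3. It was highest in AAP 3 and PBS 2, the pools lowest in lens markers (-2.06 and -2.17), but not in AAP 1, where lens markers were at -1.39. PBS 1 lay as low as HAN. With lens and muscle levels as covariates, chosen after the data were seen, the rod median was -0.04 and did not pass (adjusted p = 0.175). Of 25 oxidative phosphorylation genes 24 were lower, with a median of -0.10 (adjusted p = 0.000849; adjusted p = 0.833 with an estimated correlation). The complex I genes Ndufb5 and Ndufa9 were at -0.17 and -0.16, and the ATP synthase genes Atp5c1 and Atp5o at -0.16 and -0.14; with slide as a block the median was -0.10 (adjusted p = 0.210), and without HAN 1 it was -0.06. With quantile normalisation it was -0.05 and did not pass (adjusted p = 0.157). Of 21 unfolded protein and heat shock genes 18 were lower (median -0.11, adjusted p = 0.00504; adjusted p = 0.833 with an estimated correlation), including the chaperone Hspa5 (-0.26), Sdf2l1 (-0.22), Ddit3 (-0.18) and Hsph1 (-0.15). The median was -0.07 with slide as a block (adjusted p = 0.776), -0.06 without PBS 3 (adjusted p = 0.124) and -0.18 without PBS 1.

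Ganglion cell and lens markers were higher as lists in HAN. Of 24 ganglion cell markers 20 were higher, with a median of 0.15 (adjusted p = 0.00681; adjusted p = 0.833 with an estimated correlation). Rbpms was at 0.34, Pou4f2 at 0.31 and Ebf1 at 0.17, and Spp1 was at -0.50. The median was 0.04 with slide as a block (adjusted p = 0.845), 0.12 without PBS 2 (adjusted p = 0.156) and 0.14 without HAN 1 (adjusted p = 0.0563). All 23 lens genes were higher, with a median of 1.13 (adjusted p = 0.0173; adjusted p = 0.965 with an estimated correlation), including Crygn (1.69), Cryab (1.31) and Cryaa (0.96, 95% interval -1.07 to 2.99). The lens median was 0.03 without PBS 2 (adjusted p = 0.779), 0.93 without HAN 2 (adjusted p = 0.190) and -0.45 with slide as a block (adjusted p = 0.788). Neither list passed with normexp background correction (ganglion 0.16, adjusted p = 0.264; lens 0.99, adjusted p = 0.295). The lens list also did not pass with slide as a random block (0.97, adjusted p = 0.106).

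No named gene of the VEGF pathway passed in HAN either. Vegfa was at 0.09 (95% interval -0.10 to 0.29; another probe at 0.19), Kdr at -0.03 (-0.28 to 0.22; another probe, outside this interval, at -0.32), Flt1 at 0.08 (-0.12 to 0.27), Nrp1 at 0.05 (-0.24 to 0.35) and Pgf at 0.01 (-0.48 to 0.49), with limma adjusted p of 0.765 for Vegfa, 0.947 for Kdr, 0.809 for Flt1, 0.921 for Nrp1 and 0.993 for Pgf. The block put them at 0.16, -0.27, 0.15, 0.10 and -0.17. The VEGF list had a median of 0.03 (camera adjusted p = 0.907; 0.04 with slide as a block, adjusted p = 0.845), with Nrp2 at 0.09 (another probe at -0.01), Vegfc at -0.10 and Flt4 at -0.13. Opn1sw was at -0.01.

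The gene test called 1 transcript higher and 0 lower in HAN than in PBS, with 2363 genes at an unadjusted p under 0.05 in limma against 1194.75 by chance (1338 higher, 1025 lower). The groups did not overlap in 20.8% of genes, where chance gives 10%, and 96.9% of genes differed by less than 1.5-fold. The called transcript was again ENSMUST00000072628, which rose by 1.71 (SE 0.09, limma adjusted p = 0.00199) to -2.88 ± 0.09 in HAN (SD, n = 3). It remained past the threshold without any single array, and its change with slide as a block was 1.52 (adjusted p = 0.0727), no longer past the threshold, within a range over all alternatives of 0.000397 (array weights) to 0.789 (replicate block and slide block). The 10 curated genes with the smallest p each had an adjusted p of 0.331: Cwc25 (0.43), the semaphorin receptor Plxna3 (0.39), the transferrin receptor Tfrc (0.43), Ccnt2 (0.38), Cyp20a1 (0.68) and the synaptotagmin Syt2 (0.34) were higher, and H3c7 (-0.61), Tas2r113 (-0.50), BC053393 (-0.47) and Fkbp11 (-0.40) were lower. Adjusted over the list alone, 3 lists had 1 member past the threshold: Ciart (clock), Cdk1 (cell cycle) and Bgn (matrix).

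Apart from the VEGF list, the remaining tested lists did not pass in HAN against PBS (camera adjusted p from 0.0839 to 0.988). Medians were -0.10 for cones, 0.05 for bipolar cells, 0.01 for amacrine and horizontal cells (mean -0.00), -0.03 for Mueller glia, -0.04 for endothelial cells (mean 0.00), 0.06 for pericytes and smooth muscle (mean -0.04), -0.02 for angiogenesis regulators, -0.04 for barrier junctions, 0.05 for hypoxia targets and -0.00 for neurotrophic factors. They were -0.00 for apoptosis, -0.02 for the Nrf2 response (mean 0.04), -0.06 for immediate early genes, 0.09 for the clock, 0.03 for the cell cycle, -0.08 for glycolysis and -0.08 for matrix. Muscle was at -0.12, cornea, iris and ciliary body at -0.00, pigment epithelium at -0.24, erythrocytes at -0.09, and neutrophils and T cells at -0.09, and the sex check genes, not tested, at 0.16. The slide block, chained through AAP, called 12 lists over the whole comparison, 9 higher and 3 lower. Only rods and complement were among the lists called without it, complement in the opposite direction. It called endothelial cells (0.32, adjusted p = 0.000243), pericytes (0.44, adjusted p = 0.00216), cell cycle (0.46, adjusted p = 0.000451), matrix (0.61, adjusted p = 0.00256), pigment epithelium (0.59, adjusted p = 2.52e-06), cornea, iris and ciliary body (0.30, adjusted p = 0.000896), muscle (3.30, adjusted p = 4.35e-06) and erythrocytes (1.75, adjusted p = 0.000625) as higher. Cones (-0.20, adjusted p = 0.0459) and glycolysis (-0.17, adjusted p = 0.0459) were called as lower. In the HAN pools themselves, list means lay between -0.15 and -0.07 for muscle and between -0.17 and -0.10 for erythrocytes, against the PBS mean. The blocked values of these lists thus carry levels of the AAP pools, with AAP 1 at 5.30 and 0.63, and show no rise in HAN.

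The direct comparison of the peptides, at the same dose and time, placed muscle, rod and mitochondrial genes higher in AAP and lens and gliosis genes higher in HAN. All 14 muscle genes were higher in AAP (median 3.35, camera adjusted p = 2.19e-08; adjusted p = 0.879 with an estimated correlation), among them Acta1 (2.44), Tnni1 (1.92, above background in 2 AAP arrays and 1 HAN array), Mylpf (1.55) and Pvalb (0.93), with AAP 1 and AAP 3 the high pools. Of 28 rod genes 25 were higher in AAP, by a median of 0.14 (adjusted p = 0.000153; adjusted p = 0.879 with an estimated correlation), including Abca4 (0.35), the photoreceptor kinase Grk1 (0.29), Sag (0.28) and Gnat1 (0.21). Of 25 oxidative phosphorylation genes 19 were higher (median 0.14, adjusted p = 0.000119; adjusted p = 0.879 with an estimated correlation), including Ndufa4 (0.25), Cox7a2 (0.22), Ndufb5 (0.19) and Cox5a (0.18). All 23 lens genes were lower in AAP (median -1.41, adjusted p = 0.00209; adjusted p = 0.879 with an estimated correlation), with Mip at -2.66, Crygn at -2.43 and Gja3 at -2.29. Of 30 gliosis genes 24 were lower in AAP (median -0.45, adjusted p = 0.0149; adjusted p = 0.879 with an estimated correlation), with Timp1 at -1.63, Gfap at -1.08 (95% interval -2.07 to -0.10), the neurotrophic cytokine Cntf at -1.05 and Mt1 at 0.22.

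Within slide 2, which held AAP 2, AAP 3, HAN 1 and HAN 2, the medians were 1.99 for muscle (adjusted p = 0.00251), 0.21 for rods (adjusted p = 1.11e-05), 0.14 for oxidative phosphorylation (adjusted p = 0.00959), -0.88 for lens (adjusted p = 0.0348) and -0.44 for gliosis (adjusted p = 0.000994). Slide as a block gave the same medians, with the lens list no longer past the threshold (adjusted p = 0.0592). In AAP 2 alone against HAN, a run chosen after the data were seen, muscle was at -0.30, lens at 1.29 and gliosis at -0.18, values of a single AAP array. With quantile normalisation the rod list (0.10, adjusted p = 0.0675) and the oxidative phosphorylation list (0.07, adjusted p = 0.0675) did not pass. Array weights ended the call of the gliosis list (-0.14, adjusted p = 0.211). The gliosis list did not pass without AAP 3 (-0.12, adjusted p = 0.734), HAN 1 (-0.33, adjusted p = 0.234) or HAN 3 (-0.22, adjusted p = 0.0558). The lens list did not pass without AAP 1 (-0.99, adjusted p = 0.111) or AAP 3 (-0.62, adjusted p = 0.532), nor the rod list without AAP 3 (0.05, adjusted p = 0.0763). Without AAP 2 the lens median was -2.81 and the muscle median 5.08, and without AAP 1 they were -0.99 and 2.06, with rods at 0.22.

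No gene passed between AAP and HAN (limma, smallest adjusted p = 0.562), with 2096 genes at an unadjusted p under 0.05 against 1194.75 by chance and 14.6% of genes not overlapping, where chance gives 10%; 95.1% differed by less than 1.5-fold. The difference in Vegfa was -0.05 (95% interval -0.25 to 0.14), in Kdr -0.09 (-0.34 to 0.16), in Flt1 0.03 (-0.17 to 0.23), in Nrp1 -0.32 (-0.61 to -0.02) and in Pgf -0.46 (-0.94 to 0.03). None of these passed after adjustment. Other probes pointed the opposite way for Vegfa (0.05) and Kdr (0.22, outside the interval of the tested probe). Within slide 2 the 5 genes were at -0.03, 0.04, 0.02, -0.42 and -0.34. The VEGF list had a median of -0.07 (camera adjusted p = 0.452; -0.04 within slide 2, adjusted p = 0.216), with Vegfc at 0.22 and Nrp2 at -0.13. Opn1sw was at -0.27, Aif1 at -0.14 and Cryaa at -1.27. The 10 curated genes with the smallest p each had an adjusted p of 0.562. The muscle genes Trim54 and Pgam2 (1.77) were higher in AAP, Trim54 by at least 2.34-fold. So were the albumin family gene Afm, by at least 2.31-fold, Ppp1r36 (1.06), the membrane metalloproteinase Mmp15 (0.61) and Smyd1 (0.32, with probes that disagreed). Haus2 (-0.37), Skor1 (-0.48), Gpr183 (-0.57) and Bach2 (-0.60) were lower.

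Apart from the VEGF list, the remaining tested lists did not pass between the peptides (camera adjusted p from 0.0517 to 0.805), and 0 lists had a member past the threshold adjusted over the list alone. The closest was the microglia list (median -0.24, adjusted p = 0.0517), which was at -0.25 within slide 2 (adjusted p = 0.00145). Medians lay between -0.17 and 0.17 for the inflammatory (-0.17), complement (-0.16), Mueller (-0.09), apoptosis (-0.07), amacrine (-0.05), immediate early (-0.05), ganglion (-0.02), hypoxia (-0.03), angiogenesis (-0.03), cell cycle (-0.02), Nrf2 (-0.01), antigen presentation (-0.01, mean 0.00), clock (-0.01), erythrocyte (-0.01) and bipolar (-0.00, mean 0.03) lists, and for glycolysis (0.01), neurotrophic factors (0.01, mean -0.05), barrier junctions (0.01, mean -0.15), matrix (0.01, mean -0.00), endothelial cells (0.03), neutrophils and T cells (0.03), cones (0.04), the unfolded protein response (0.05) and interferon (0.17). The pericyte list was at -0.13, pigment epithelium at 0.22 and cornea, iris and ciliary body at -0.50, and the sex check genes, not tested, at 0.02. The slide block called pericytes (-0.42, adjusted p = 0.00905), microglia (-0.25, adjusted p = 0.00227), complement (-0.40, adjusted p = 0.000368), inflammation (-0.24, adjusted p = 0.00905), cell cycle (-0.14, adjusted p = 0.00403), matrix (-0.19, adjusted p = 0.0166), cornea, iris and ciliary body (-0.59, adjusted p = 0.0296) and erythrocytes (-0.65, adjusted p = 0.00224) as lower in AAP. The same lists passed within slide 2, with barrier junctions besides (-0.15, adjusted p = 0.0364).

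Both peptide comparisons used the same PBS arrays. Of the lists, 6 were lower and 1 was higher in both. No list call in the 3 comparisons held with an estimated correlation or with fry (lowest fry adjusted p = 0.440 for AAP against PBS, 0.725 for HAN against PBS and 0.925 for AAP against HAN). The log2 differences of AAP and HAN from PBS correlated at 0.254 across genes, which are not independent replicates, while groups simulated without any effect against these controls gave 0.497 (0.454 to 0.560 over 100 simulations). The covariance was 0.0170 against 0.0353 in the simulations, and 62.3% of genes had the same sign against 66.6%. Agreement between the comparisons was thus not above these simulations. They drew genes independently and gave all groups the same spread, while AAP arrays spread more (median SD 0.14 against 0.10 in PBS and HAN). Their range is therefore no firm bound, and whether agreement lay below that of shared controls alone stays undecided. Genes at an unadjusted p under 0.05 in both numbered 367 higher and 165 lower. No value under shared controls was computed for these gene and list overlaps, so they do not show a response common to both peptides.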

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

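The tests of slide, dilution and scaling for the glial and immune lists, and of a response to the peptides for the lens list, were chosen only after the result was seen. The lists below were singled out because AAP and HAN differed from each other in the direct test. By median log2, AAP minus HAN, the rod list differed by 0.14 (25 of 28 genes higher in AAP) and the oxidative phosphorylation list by 0.14 (19 of 25 higher), each with an adjusted p = 0.879 with an estimated correlation, not past the threshold.

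The gliosis list differed between AAP and HAN by -0.45 (adjusted p = 0.879 with an estimated correlation) and, with the microglia and complement lists, was lower in AAP than in PBS, with a median of -0.72 over the members of the 3 lists (adjusted p = 0.564 with an estimated correlation for each list). Dilution of retinal RNA by lens or muscle RNA would lower neuron, glial and immune transcripts of the retina alike. Neuron and photoreceptor markers had a median of 0.0364 (SD 0.158) in the same comparison. Scaling shifts all genes of an array by the same amount, so this value alone cannot show whether dilution occurred. Scaling leaves the gap between 0.0364 and -0.72 in place, and an equal dilution of retinal transcripts would not open it. The gap argues against dilution as the cause of the lower lists. The scaling between arrays is argued against by a median of -0.58 or lower in each of 4 other settings. These were median scaling, quantile normalisation, normexp and the value table. Median scaling could move it little, since the median difference over all genes was -0.0045. Slide cannot be told apart from the group: with slide as a block the median was -0.36, on AAP 1 alone, since no other AAP array shared the PBS slide. A response of glia and microglia to AAP stays open and untested. So do differing amounts of cornea, iris and ciliary body tissue. Its markers had means of 0.86, -0.05 and -1.98 in AAP 1, AAP 2 and AAP 3, and medians of -0.29, -0.06 and -2.06. The means of the pigment epithelium and barrier junction lists fell in the same order, so this order is not particular to that tissue.

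The skeletal muscle list differed between AAP and HAN by 3.35 (adjusted p = 0.879 with an estimated correlation). Of a second list of muscle genes, 81.25% (13 of 16) lay above all PBS arrays on both AAP 1 and AAP 3, which is consistent with muscle tissue in those pools, where Mb stood 505-fold and 164-fold above the PBS mean. The test of a response of the retina to AAP did not decide. The second list was at -0.10 in AAP 2 against the PBS mean, 2.29 in AAP 1 and 0.92 in AAP 3. This last value missed the level of 1 that the test had required of both arrays. The first muscle list stood at 5.30, -0.35 and 4.03 in AAP 1, AAP 2 and AAP 3, and between -0.14 and 0.24 in PBS. These values argue against a response common to every AAP pool, though AAP 2 is a single array.

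The lens list differed between AAP and HAN by -1.41 (adjusted p = 0.879 with an estimated correlation). Its level followed that of a second lens list of 7 measured genes over the 9 arrays (Pearson's r = 0.988, exact permutation p = 2.76e-05; Spearman's rho = 0.967, exact permutation p = 0.000165), and r was 0.982 without PBS 2 and AAP 3, the arrays farthest from the median. Lens genes would move together whatever raised them, so this does not tell lens tissue from a response. Lens tissue carried into the pools in differing amounts is a candidate explanation. The PBS arrays differed among themselves by 3.32 and overlapped both peptide groups, so the lens list varied without any peptide. A response to the peptides on top of this spread cannot be excluded with 3 pools a group. AAP 2 (2.29), HAN 2 (1.44) and HAN 3 (1.24) lay above the highest PBS array (1.16). AAP 1 (-1.39), AAP 3 (-2.06) and HAN 1 (0.58) lay within the PBS range.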

How the results depend on the processing

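The runs without AAP 1 and AAP 3, and with lens and muscle levels as covariates, were chosen only after the data were seen; the first leaves a single AAP array, assumed to vary like the other groups. Signal over background limits dim genes: only 71.6% to 79.2% of spots were well above background, and a gene below it in a group has only a bound. Where no reason is given, the cause was not tested. Of the list results, 207, 216 and 119 kept direction and side of the threshold in AAP against PBS, HAN against PBS and AAP against HAN, and 40, 26 and 17 kept the direction but no longer passed. The direction turned in 4, 10 and 2. The 207 include values within slide 1, which had no test and were counted where they lay close to the reported value. The replicate numbers were not taken as pairs: 3 of 9 pairs with a number in common correlated above 0.1 (-0.283 to 0.401), and 0 of 9 arrays correlated best with their own number in both other groups. PBS 1 and AAP 1 (0.401), and AAP 2 and HAN 2 (0.213), did correlate best with each other, and each pair shared a slide. The highest correlation of any pair, 0.538, was between PBS 2 and AAP 3, which shared neither a number nor a slide.

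In AAP against PBS, genes past the threshold numbered 0 with median scaling, no filter on dim probes, normexp, only the compared groups, quantile normalisation, the replicate block, the replicate and slide blocks, the covariates and without AAP 1 and AAP 3, and 60 with slide as a fixed block, 1 of them shared with the reported count. They ranged from 0 (without AAP 3 or any PBS array) to 12 (without AAP 2, 8 of them in the muscle lists) over left-out arrays. Lists past the threshold numbered 16 with the covariates, and 5 (without AAP 3) to 16 (without AAP 1) over left-out arrays. The reported 10 (2 higher, 8 lower) became 11 with slide as a block (6 higher, 5 lower, 3 shared) and 9 with the replicate and slide blocks (5 higher, 4 lower, 4 shared: gliosis, microglia, inflammation and muscle). List medians that turned included 0.0660 for antigen presentation with slide as a block, as within slide 1. Without AAP 1 and AAP 3, they included -0.36 for muscle and 0.0101 for interferon, values of a single AAP array. The interferon median stayed negative with slide as a block (-0.0113), while its test turned higher.

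In HAN against PBS, genes numbered 3 with array weights, 2 with slide as a block (0 shared), 0 with normexp, the replicate block and the covariates, and 1 to 3 over left-out arrays (3 without HAN 1 or HAN 2). Lists numbered 7 with the replicate and slide blocks (2 shared, interferon and microglia), which leave 2 residual degrees of freedom, and 10 to 13 over left-out arrays. Slide as a block gave 12 lists, 9 higher and 3 lower, 2 of them shared with the reported 11, of which 2 were higher and 9 lower. With slide as a block, chained through AAP, medians turned to 0.11 for antigen presentation, 0.44 for complement, 0.11 for inflammation, 0.15 for gliosis and -0.45 for lens. With the replicate and slide blocks they turned to -1.63 for lens, 0.0393 for oxidative phosphorylation and 0.0546 for the unfolded protein response. The lens test also turned with the covariates (median 0.0098), which hold the lens level itself, and without PBS 2 (0.0337); over left-out arrays the lens median ran from 0.0337 to 1.63.

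In AAP against HAN, genes numbered 0 in every other setting, and 0 to 12 over left-out arrays (12 without AAP 2, 1 without HAN 2). Lists numbered 3 with quantile normalisation, where rods and oxidative phosphorylation no longer passed, 13 with the covariates, 12 with slide as a block, 14 within slide 2, and 4 (without HAN 1) to 10 (without AAP 1) over left-out arrays, with 8 without HAN 2. Of the reported 5 lists, 4 also passed with slide as a block, 5 within slide 2, 2 without AAP 3 and 1, muscle, with the replicate and slide blocks. Without AAP 1 and AAP 3 the lens median turned to 1.29 and the muscle median to -0.30.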

Other observations

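The tests of all 6 peptide arrays against PBS were chosen only after the result was seen. Taking AAP and HAN arrays as 1 group of 6, reactive gliosis genes were lower than in the 3 PBS arrays by 0.67 on the log2 scale, with 6 of 6 peptide arrays below all PBS arrays. Microglia genes were lower by 0.63 (5 of 6), inflammatory genes by 0.58 (4 of 6), interferon-stimulated genes by 0.53 (3 of 6), complement genes by 0.51 (4 of 6) and antigen presentation genes by 0.36 (4 of 6). Of the 84 splits of the 9 arrays into 6 and 3, as large a difference in either direction came from 4 for gliosis (exact p = 0.0476), 5 for microglia (exact p = 0.0595), 8 for inflammation (exact p = 0.0952), 15 for complement (exact p = 0.179), 16 for antigen presentation (exact p = 0.190) and 17 for interferon (exact p = 0.202). After Benjamini-Hochberg adjustment over the 6 lists none passed (adjusted exact p from 0.179 to 0.202), and the differences of largest size in other splits were 0.85, 0.84, 0.78, -0.81, -0.55 and 0.85 in the order of those splits. As a hypothesis, glial and immune genes may be lower after either peptide, which these tests leave undecided, and slide stays open because no HAN array shared the PBS slide.

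With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In AAP against PBS, 2 splits gave as many genes (1 in the real split, 19 in the highest other) and 6 as many lists (10 against 21). The split with 19 genes set AAP 1, AAP 3 and PBS 2 against AAP 2, PBS 1 and PBS 3, which are the arrays low and high in lens genes, and points to a structure of the samples other than the groups. In HAN against PBS, 1 split gave as many genes (1 against 0) and 6 as many lists (11 against 15). In AAP against HAN, 10 gave as many genes (0 against 7) and 9 as many lists (5 against 15).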
